A study of Homo sapiens with 4 samples.

How the data were processed

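RNA was measured in MDA-MB-231 cells, a human triple-negative breast cancer line, 72 h after transfection with siRNA against ELK1 or against NFYA. Each of 4 Agilent whole-genome arrays compared an siRNA-transfected culture with a mock-transfected culture of the same line. Per the labels, the siRNA sample carried Cy3 and the mock sample Cy5 on all arrays, with no dye swap. Each siRNA target had 2 arrays, whose titles end in siRNA1 and siRNA2 and which are numbered 1 and 2 here. The labels do not say whether these numbers stand for different siRNAs, whether the cultures were separate or whether the arrays shared mock RNA. The p-values therefore measure the spread between arrays, which may be technical.

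Image analysis used Agilent Feature Extraction 9.5, per the submitters' processing notes, and version 9.5.3.1 per the file headers. The spot values used here are mean spot intensity and median local background per channel on a linear scale, per the file headers, with no normalization. The deposited log10 ratios in the same files are Cy5 over Cy3 after the scanner software's own background and dye correction, per the file headers. The series-wide value table holds log10 ratios that the authors deposited with the opposite sign, siRNA over mock. Its values matched the negated scanner ratios within 0.001 for 45015 features on each array, and each column's median over non-control features was 0. Probe coordinates follow build hg17, per the file headers.

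Intensities were background-corrected with normexp (offset 50) and normalized within each array by loess, with control and outlier spots at weight 0, in limma 3.58.1 under R 4.3.3. Each log ratio was turned to log2(siRNA/mock), so values above 0 mean more signal from the siRNA culture. Control spots and spots with an outlier flag were left out, and saturated spots were kept. A probe was used if it was well above background in at least 1 channel on at least 2 arrays, which kept 30549 of 41000 probes. Spots of a probe and then probes of a gene were averaged, giving 23107 genes, of which 5626 had several probes. Through RefSeq accessions of GRCh38.p14, 23434 probes received current symbols, 1745 more took the symbol of accession-matched probes with the same name in the files, and 15821 kept the name in the files.

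All 4 arrays entered 1 limma model with a mean per group and empirical Bayes moderation (2 residual degrees of freedom, 5.89 prior degrees of freedom). It tested each group against 0 and the ELK1 minus NFYA difference, at a Benjamini-Hochberg adjusted p below 0.05. Values after ± are moderated standard errors (SE) from this model. They draw on the spread in both groups and on the prior, not on the 2 arrays of a group alone. Gene-specific dye effects were part of each comparison with mock and cancelled in the difference. Before the data were examined, 25 gene lists were fixed. They were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. Camera with an estimated correlation works with the 2 residual degrees of freedom, so its p-values are large even where that correlation is low. The cholesterol list under ELK1 siRNA had an estimated correlation of -0.033, yet its camera p went from 1.33e-08 to 0.0239. A call lost there therefore need not reflect correlated genes. Other lists had higher estimates: 0.65 for ribosomal proteins, 0.34 for antigen presentation, 0.19 for histones and 0.16 for replication. For those the preset 0.01 lies below the estimate, so camera p-values at the preset correlation may be too small.

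The rule for named genes, fixed with the lists, took ELK1 and NFYA, the 8 highest and 8 lowest passing genes with a symbol, the same sign on both arrays and signal well above background in at least 1 channel on every array compared, and the 4 members with the smallest p in each list described. Where fewer than 3 genes passed, it took the 5 with the smallest p in each direction. Because the 8 highest genes were all saturated in the mock channel, the 8 highest without a saturated spot were added after seeing the data. A saturated mock spot understates mock RNA, so its siRNA/mock ratio is only an upper bound.

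The fit was tested on simulated data of 23047 genes, 200 of them changed singly. A further list of 30 genes was given a log2 shift of -0.3, and camera at the preset correlation called it in every comparison. Each gene's residual SD, estimated on 2 degrees of freedom, was taken as its true spread. The simulated spreads can therefore be more uneven than the real ones, and recovery on the real arrays may differ. At 2-fold, 61 of 100 changed genes were recovered for ELK1 siRNA and 68 of 100 for NFYA siRNA. At 1.5-fold, 17 and 25 of 100 were recovered, with 0 and 1 calls among 22817 unchanged genes. For the ELK1 minus NFYA difference, 0 of 100 genes were recovered at 1.5-fold and 0 of 100 at 2-fold. Of the 100 at 2-fold, 98 had an unadjusted limma p below 0.05.

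The number of arrays limits the precision of every value. Alternatives changed the background correction, the normalization, the filter on dim probes, the summary of probes, the variance prior, the arrays in the fit, the replicate number as a block, outlier flags, the thresholds and the use of the deposited ratios. Saturated spots left out and a correction for the base composition of the 60-base probes were added after seeing the data. Slide and scan session could not be tested, because all arrays came from 1 slide scanned together. Figures were drawn with matplotlib 3.10.9.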

Results

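Gene expression was profiled in MDA-MB-231 breast cancer cells 72 h after transfection with siRNA against ELK1 or NFYA. ELK1 is an ETS-family transcription factor that acts with serum response factor. NFYA is the sequence-specific subunit of the CCAAT-binding complex NF-Y. The term knockdown below names the siRNA used, since a fall of ELK1 RNA was not established on these arrays. Each knockdown was hybridised against mock-transfected cells on 2 two-colour arrays. Median spot intensity was 105 to 146 in the siRNA channel and 284 to 319 in the mock channel, and 69.0% to 75.0% of spots lay well above background. In the mock channel 1243 to 1433 spots per array were saturated, against 0, 1, 102 and 2 in the siRNA channel.

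The targeted genes were examined first. The NFYA probe, at chromosome 6:41173331-41173390 in hg17, fell after NFYA siRNA to a log2 ratio of -0.71 ± 0.08 (moderated SE, n = 2, limma adjusted p = 0.00312). On the arrays it was at -0.77 and -0.65. Under ELK1 siRNA the NFYA ratio was -0.25 ± 0.08 (adjusted p = 0.0868), and the difference between the knockdowns was 0.46 ± 0.11 (limma adjusted p = 0.924). The ELK1 probe, at chromosome X:47252079-47252138, was not well above background in the siRNA channel of both ELK1 arrays, so only a bound is available. From per-channel values after loess and Aquantile scaling, mock exceeded ELK1 siRNA at least 1.09-fold on average. That bound remains open to dye bias, and its direction depends on the scaling. The fitted ELK1 ratio was -0.13 ± 0.09 under ELK1 siRNA (adjusted p = 0.357) and 0.17 ± 0.09 under NFYA siRNA (adjusted p = 0.398). In the deposited ratios ELK1 was at -1.09 and -1.83 on the ELK1 arrays, a mean of 36.3% of mock (limma adjusted p = 0.0368). On the NFYA arrays it was at -0.36 and 0.34, a mean of 99.1% of mock. These percentages are not exact levels. The siRNA channel was not well above background on either ELK1 array, and was so on only 1 NFYA array. Median centring turned the ELK1 ratio to 0.35 (limma adjusted p = 0.0228). The NFYA call was lost when either NFYA array was left out (adjusted p = 0.0906 without array 1 and 0.0708 without array 2).

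The first comparison asked which transcripts differed from mock after ELK1 siRNA. EGR1 is an immediate-early zinc-finger factor and classic target of ELK1 and serum response factor. It fell by 1.56 ± 0.15 on the log2 scale (moderated SE, n = 2, limma adjusted p = 0.00120), with -1.38 and -1.74 on the arrays. TMEM154 fell by 1.65 ± 0.11. The serine synthesis enzyme PSAT1 (-1.46 ± 0.17) and the transsulfuration enzyme CTH (-1.32 ± 0.12) fell as well. S100P was at -1.21 ± 0.08, the cytokine receptor subunit IL20RB at -1.17 ± 0.10 and the metalloprotease ADAMTS6 at -1.22 ± 0.24, the last with unequal arrays (-0.61 and -1.84), and it did not pass with the deposited ratios.

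Among genes without a saturated spot, the highest was QARS1, the glutaminyl-tRNA synthetase, at 1.21 ± 0.12. GMFG (1.03 ± 0.13), NUDC (0.96 and 1.04 on the arrays), the lysyl-tRNA synthetase KARS1 (0.92 ± 0.10), the deacetylase SIRT2 (0.90 ± 0.08) and the chemokine CXCL1 (0.90 ± 0.12) followed. The class I pseudogene HLA-H (1.03 ± 0.25) and the RNase P subunit RPP25 (0.88 ± 0.20) also passed, but neither passed without ELK1 siRNA array 2 (0.56 and 0.46). The 8 highest of all passing genes, RPL19, RPLP0P2, TUBA1B, RPLP0, HCN2, KLC3, RPS4X and RPL11, had fitted ratios of 1.43 to 1.58 with the mock channel saturated on both arrays, which makes each ratio an upper bound.

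The cholesterol list fell, with 12 of 26 members lower, 0 higher and a median of -0.33 (16 lower adjusted over the list alone; camera adjusted p = 1.28e-07; adjusted p = 0.298 with an estimated correlation). Among its members, INSIG1, which holds SREBP precursors in the endoplasmic reticulum, was at -1.01 ± 0.08, the sterol transporter STARD4 at -0.75 ± 0.08, and DHCR7, the last enzyme of the pathway, at -0.89 ± 0.08. In the fatty acid list 6 of 19 members fell and 1 rose, with a median of -0.22 (10 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.00631; adjusted p = 0.421 with an estimated correlation). SCD, the stearoyl-CoA desaturase, was at -0.93 ± 0.10, the phosphatidate phosphatase LPIN1 at -0.79 ± 0.09, the desaturase FADS2 at -0.65 ± 0.08 and the acyl-CoA synthetase ACSL3 at -0.51 ± 0.09. The list was not called without ELK1 siRNA array 1 (adjusted p = 0.0780). Of the amino acid response list 14 of 32 members fell and 0 rose, with a median of -0.35 (21 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.28e-07; adjusted p = 0.298 with an estimated correlation). Besides PSAT1 and CTH, DDIT4, an inhibitor of mTORC1, was at -0.64 ± 0.08, and the pseudokinase TRIB3 passed with mock saturated on 1 ELK1 array, so that its -0.78 is an upper bound.

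Cytosolic ribosomal proteins had 67 of 86 members called higher and a median of 0.73 (73 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.31e-44; adjusted p = 0.421 with an estimated correlation), yet 80 members had a saturated spot and the 6 without one had a median of 0.026. RPL27 (1.37) and RPLP2 (1.16) were among the saturated members, and leaving out saturated spots turned the list's median to -0.014. Oxidative phosphorylation (24 of 81 higher, median 0.10; 31 higher and 3 lower adjusted over the list alone; camera adjusted p = 1.90e-05, turned to a median of -0.47 by median centring) was led by COX8A, NDUFS5, COX7A2 and ATP5MK, all saturated in mock. The proteasome list (11 of 37 higher, median 0.13; 17 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000202, turned to -0.39 by median centring) held PSMD11 at 0.61 ± 0.10 without saturation and PSMB1, PSMB7 and PSMB4 with it. Its median was 0.24 without ELK1 siRNA array 2. The 38 oxidative phosphorylation genes without a saturated spot had a median of -0.026, and leaving out saturated spots turned the list to -0.032 and ended its call (adjusted p = 0.550). For both lists the adjusted p was 0.421 with an estimated correlation.

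Mitotic genes were higher in 9 of 42 and lower in 2, with a median of 0.12 (15 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.000393; adjusted p = 0.421 with an estimated correlation), turned to -0.39 by median centring. AURKA, the Aurora A kinase, was at 0.61 ± 0.09 and the CDK phosphatase CDC25C at 0.37 ± 0.08, while PTTG1 and CKS1B were saturated in mock; centring turned AURKA and CDC25C below 0 too. Histones were higher in 7 of 66 with a median of 0.22 (9 higher adjusted over the list alone; camera adjusted p = 2.72e-06; adjusted p = 0.489 with an estimated correlation), turned to -0.25 by median centring. The leading members H4C3, H2AZ1, H3-3A and H2AX were saturated in mock, and the probes of H3-3A disagreed in sign. The list's median was 0.0034 on ELK1 array 1 and 0.41 on array 2, so that its call ended without array 2 (adjusted p = 0.0879). Heat shock genes were higher in 5 of 23 with a median of 0.079 (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0288; adjusted p = 0.421 with an estimated correlation), turned to -0.27 by median centring. The HSP90 co-chaperone AHSA1 was at 0.69 ± 0.10, and HSPA8, HSPE1 and HSPD1 were saturated in mock. The heat shock call ended without ELK1 siRNA array 1 (adjusted p = 0.113), without saturated spots (0.110), under the stricter filter (0.0711), with the deposited ratios (0.135) and with the brightest probe per gene, which turned the median to -0.046. Antigen presentation genes were higher in 3 of 25 and lower in 1, with a median of 0.12 (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000286; adjusted p = 0.506 with an estimated correlation), turned to -0.12 by median centring. The median was 0.065 without ELK1 siRNA array 2 and 0.22 without array 1. HLA-G, HLA-C and B2M were the higher members, all saturated in mock, and RFXAP, a subunit of the factor that activates class II genes, was at -0.46 ± 0.10.

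In total 1957 of 23105 genes passed, 1001 higher and 956 lower, and 595 of them differed by at least 1.5-fold. Among the higher genes 528 were saturated in mock on both arrays, and 1410 of the passing genes, 472 higher and 938 lower, had no saturated spot. A refit without saturated spots called 447 genes, 108 higher and 339 lower. The count was 671 without ELK1 siRNA array 2, 4712 without array 1 and 1216 without either NFYA array, and median centring gave 2910 higher and 9739 lower while moving the median of all genes from -0.022 to -0.19. The other 15 lists did not pass, with medians from -0.026 to 0.071 and the smallest adjusted p at 0.0909. Leukocyte and stromal markers, which could show other cells, had 0 of 15 members passing in limma under either siRNA and medians of -0.018 and -0.035. Among them was the immediate-early list, at -0.011, in which EGR1, ATF3 and DUSP1 fell (the last, at -0.71 ± 0.11, chosen after its value was seen) and 27 of 30 members did not pass.

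**Figure D1:**
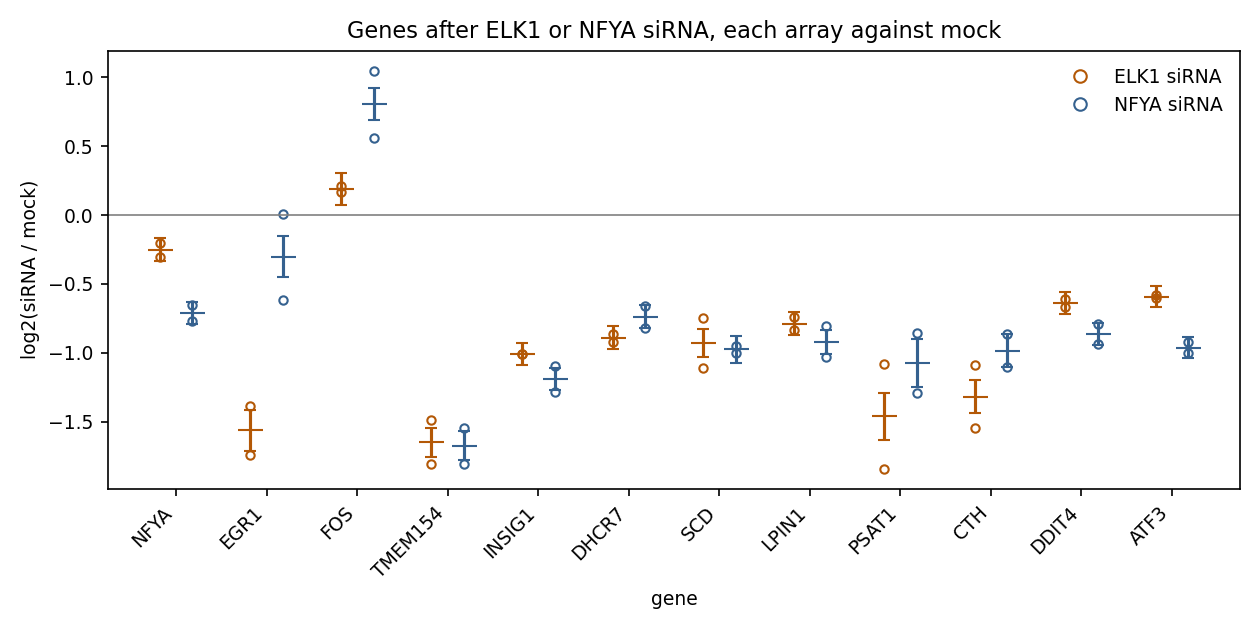
Log2 ratio of siRNA over mock (vertical axis) for 12 genes (horizontal axis). Open circles are single arrays, 2 for ELK1 siRNA in orange and 2 for NFYA siRNA in blue. Bars give the fitted mean ± moderated SE. EGR1 lies at -1.38 and -1.74 on the ELK1 arrays and at 0.010 and -0.62 on the NFYA arrays, whereas TMEM154, INSIG1 and SCD lie well below 0 on all 4.

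The second comparison asked which transcripts differed from mock after NFYA siRNA. TMEM154 again had the lowest ratio, falling by 1.68 ± 0.11 on the log2 scale (moderated SE, n = 2, limma adjusted p = 0.00119). The sterol regulator INSIG1 was at -1.19 ± 0.08. PSAT1 (-1.07 ± 0.17), CTH (-0.99 ± 0.12), the nicotinamide methyltransferase NNMT (-0.98 ± 0.10), SCD (-0.98 ± 0.10) and the stress-induced factor ATF3 (-0.96 ± 0.08) were also among the lowest passing genes. Under NFYA siRNA PSAT1 kept its call in 13 of 18 alternatives.

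Without a saturated spot, the highest gene was FOS, an immediate-early AP-1 subunit, at 0.81 ± 0.12 with 1.05 and 0.56 on the arrays. The growth factor BMP4 (0.78 ± 0.17), ZNF114 (0.74 ± 0.12), the pregnancy glycoprotein PSG4 (0.67 ± 0.08), the ubiquitin ligase MARCHF4 (0.67 ± 0.09), SUN3 (0.66 ± 0.13), the cytokine IL11 (0.66 ± 0.13) and the vasoconstrictor peptide EDN1 (0.65 ± 0.08) also passed. Each of these 8 lost its call without at least 1 of the NFYA arrays, and without array 2 BMP4, SUN3 and IL11 were at 0.40, 0.43 and 0.42. Over 18 alternatives IL11 kept its call in 12, and BMP4 and SUN3 kept theirs in 13 each. Among the highest of all passing genes, TUBA1B, RPS4X, RPL11, RPLP0P2, RPL19, RPL27 and ANAPC11 had ratios of 1.24 to 1.37 with mock saturated on both arrays.

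In the cholesterol list 8 of 26 members fell and 0 rose, with a median of -0.30 (15 lower adjusted over the list alone; camera adjusted p = 1.09e-10; adjusted p = 0.213 with an estimated correlation). Besides INSIG1, STARD4 was at -0.81 ± 0.08 and DHCR7 at -0.74 ± 0.08. In the fatty acid list 6 of 19 fell and 0 rose, with a median of -0.30 (10 lower adjusted over the list alone; camera adjusted p = 1.90e-06; adjusted p = 0.257 with an estimated correlation). LPIN1 was at -0.92 ± 0.09, and the desaturases FADS1 and FADS2 were at -0.78 ± 0.09 and -0.64 ± 0.08. The amino acid response list had 16 of 32 lower and 1 higher, with a median of -0.39 (22 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.13e-15; adjusted p = 0.213 with an estimated correlation). DDIT4 was at -0.86 ± 0.08, the serine synthesis phosphatase PSPH at -0.77 ± 0.09 and TRIB3 at -0.76 ± 0.08.

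Inflammatory genes of the NF-kB list had 2 of 27 members lower, 0 higher and a median of -0.084 (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0259; adjusted p = 0.518 with an estimated correlation). The cytokine IL6 was at -0.46 ± 0.08 and the chemokine CXCL8 at -0.48 ± 0.09, while BIRC3 (-0.32 ± 0.09) and NFKBIA, which was saturated in mock, did not pass. The calls of IL6 and CXCL8 ended with the deposited ratios (-0.45 and -0.43), in the refit without saturated spots, which left both ratios in place, and without either NFYA array. Over all alternatives their ratios were at most -0.45 and -0.37. The list was not called without NFYA siRNA array 1 (median -0.15, adjusted p = 0.113) or without saturated spots (adjusted p = 0.0964), and its median was -0.13 without array 2. The replication list was higher by its test with 2 of 45 members called (median 0.12; 3 higher adjusted over the list alone; camera adjusted p = 0.000710; adjusted p = 0.539 with an estimated correlation), turned to -0.22 by median centring. TK1 and MCM7, its called members, were saturated in mock, and MCM4 (0.38 ± 0.09) and FEN1 (0.49 ± 0.15, and 0.20 without NFYA siRNA array 2) did not pass. Ribosomal proteins had 59 of 86 called higher and a median of 0.69 (73 higher and 2 lower adjusted over the list alone; camera adjusted p = 3.30e-54; adjusted p = 0.518 with an estimated correlation), with a median of -0.031 over the 7 unsaturated members. RPLP2 and RPS20 were among those saturated, and leaving out saturated spots turned the list's median to -0.060. Oxidative phosphorylation (20 of 81 higher and 1 lower, median 0.035; 25 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.00512) and the proteasome (4 of 37 higher and 1 lower, median 0.079; 6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0134) were turned to -0.37 and -0.26 by median centring, and oxidative phosphorylation to -0.076 without saturated spots. Their leading members COX8A, NDUFS5, COX7A2, COX6A1, PSMB1, PSMB4, PSMB7 and PSMA6 were saturated in mock. Without NFYA siRNA array 2 the oxidative phosphorylation median was -0.032, and without array 1 the medians were 0.071 and 0.17. The proteasome was not called without NFYA siRNA array 2 (median 0.031, adjusted p = 0.302) or without saturated spots (0.0964), and the adjusted p of both lists was 0.539 with an estimated correlation.

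In total 833 of 23103 genes passed, 495 higher and 338 lower, and 406 differed by at least 1.5-fold. Among the higher genes 432 were saturated in mock on both arrays, and 392 of the passing genes, 63 higher and 329 lower, had no saturated spot. A refit without saturated spots called 118 genes, 10 higher and 108 lower. The count was 164 without NFYA siRNA array 1, 76 without array 2 and 1765 without either ELK1 array, with 30 of the 46 named passing genes lost in the smallest case, and median centring gave 674 higher and 5019 lower while moving the median of all genes from -0.0087 to -0.13. The other 17 lists did not pass, with medians from -0.091 (histones) to 0.12 and the smallest adjusted p at 0.0614. Antigen presentation genes had a median of -0.061 but a mean of 0.015.

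The third comparison set the knockdowns against each other. EGR1 was lower under ELK1 siRNA than under NFYA siRNA by a log2 difference of -1.26 ± 0.21, and SIRT2 (0.74 ± 0.12), the histone H3C15 (0.996 ± 0.16), PQBP1 (0.74 ± 0.12) and PSMC3IP (0.77 ± 0.13) were higher, but none of these passed the limma test (adjusted p = 0.924 for each). SYBU (-0.74 ± 0.13), GSG1 (-0.81 ± 0.15), the chemokine CCL26 (-0.57 ± 0.11) and MPP4 (-0.74 ± 0.15) had the next smallest p among the lower genes, and the probes of CCL26 disagreed in sign under NFYA siRNA. RPL35 had the smallest adjusted p (0.188) and a fitted difference of 1.45, with mock saturated on all 4 arrays, so that its size is not measured. In limma 0 of 23101 genes passed and 781 had an unadjusted p below 0.05. With 2 arrays per group, the count does not show that the knockdowns acted alike. The simulated test recovered no planted 2-fold change. It cannot settle what the real test could find, because its spreads came from 2 residual degrees of freedom. Without ELK1 siRNA array 1, 311 genes passed, 1 passed without ELK1 siRNA array 2, and median centring gave 2.

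By set test, 9 lists were higher under ELK1 siRNA than under NFYA siRNA, with 0 of their members passing singly over all genes. With an estimated correlation 0 of the 9 lists passed (adjusted p = 0.973 for ribosomal proteins and 0.527 for each of the others). Antigen presentation had a median difference of 0.32 over 25 genes (camera adjusted p = 2.43e-09), with HLA-DPB1 at 0.49 ± 0.13, HLA-DRB1 at 0.53 ± 0.15, HLA-DPA1 at 0.37 ± 0.11 and HLA-DMB at 0.36 ± 0.12. Without ELK1 siRNA array 2 HLA-DRB1 was at 0.33. The list median was 0.0998 without ELK1 siRNA array 2, 0.16 without NFYA siRNA array 1 and 0.13 with median centring. Histones had a median difference of 0.26 over 66 genes (3 higher adjusted over the list alone; camera adjusted p = 2.55e-15), with H2BC8 at 0.68 ± 0.12, H2BC14 at 0.69 ± 0.15 and H2AC20 at 0.58 ± 0.19. Without ELK1 siRNA array 2 H2AC20 was at 0.28 and without array 1 at 0.88. The histone median was 0.096 without ELK1 siRNA array 2, 0.42 without array 1 and 0.099 with median centring. The NF-kB list differed by a median of 0.10, brought to -0.0049 by median centring (camera adjusted p = 0.000377; fry adjusted p = 0.0187, against 0.138 to 0.934 for the other 8 lists), with CXCL1 at 0.61 ± 0.17, CXCL2 at 0.80 ± 0.24, CCL20 at 0.48 ± 0.16 and CXCL8 at 0.35 ± 0.12. Without ELK1 siRNA array 2 CXCL1, CXCL2 and CCL20 were at 0.39, 0.39 and 0.30, and without array 1 CXCL2 was at 1.22.

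Hypoxia and glycolysis genes differed by 0.12 (camera adjusted p = 0.00418; PFKFB4 0.33 ± 0.17 and P4HA2 0.31 ± 0.16, which were 0.14 and 0.083 without ELK1 siRNA array 2, with GAPDH and PGK1 saturated in mock on all 4 arrays) and mitotic genes by 0.057 (camera adjusted p = 0.0106; AURKA 0.49 ± 0.12, CCNA2 0.44 ± 0.11, CDC25C 0.41 ± 0.11, NUSAP1 0.37 ± 0.11), and median centring turned these medians to -0.040 and -0.15. Smaller differences were found for fatty acid synthesis (0.081, camera adjusted p = 0.0230; ELOVL6, FADS1, ACSL3, AGPAT2), the proteasome (0.066, adjusted p = 0.0134; PSMA7, PSMC6, PSMA4, PSMB8), ribosomal proteins (0.050, adjusted p = 0.0164, 1 higher adjusted over the list alone; RPL35, RPL4, RPL39L, RPLP0) and oxidative phosphorylation (0.036, adjusted p = 0.0134; NDUFA2, ATP5F1B, NDUFA11, COX7B2), and all 4 medians fell below 0 under median centring. The hypoxia list lost its call without ELK1 siRNA array 1 (adjusted p = 0.0658), and the mitotic, fatty acid, proteasome, ribosomal and oxidative phosphorylation lists each lost theirs without at least 1 array. Without single arrays these 5 medians ranged from 0.030 to 0.12, 0.053 to 0.14, 0.026 to 0.15, -0.087 to 0.19 and 0.00034 to 0.084 in turn. Saturated spots affected 80 of 86 ribosomal, 44 of 81 oxidative phosphorylation and 15 of 37 proteasome members, so the sizes of these differences are not exact. The ribosomal call also ended without saturated spots (camera adjusted p = 0.154) and with the base composition correction (0.0867). It ended without background correction (0.0562) and with the deposited ratios (0.293) as well. In the 7 lists other than histones and ribosomal proteins 0 members passed adjusted over the list alone. The other 16 lists had medians from -0.054 to 0.084 and did not pass (smallest camera adjusted p = 0.0837); the immediate-early list had a median of 0.055 and a mean of -0.032.

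**Figure D2:**
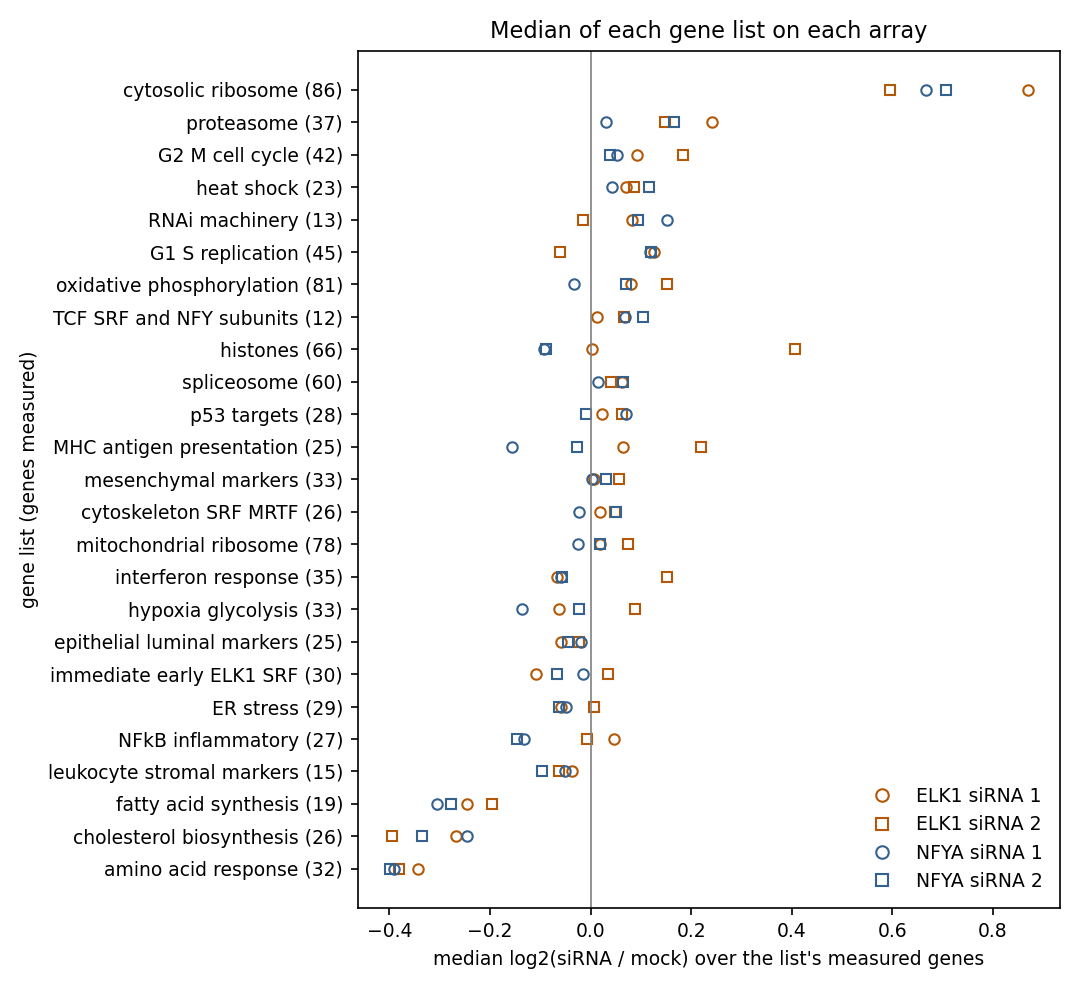
Median log2 ratio of siRNA over mock (horizontal axis) for each of 25 gene lists (vertical axis, number of measured genes in brackets). Circles are arrays numbered 1 and squares arrays numbered 2, orange for ELK1 siRNA and blue for NFYA siRNA. Amino acid response, cholesterol and fatty acid lists lie below 0 on all 4 arrays, ribosomal proteins lie above 0 with most members saturated in mock, and histones are raised on ELK1 siRNA array 2 (0.41).

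The overlap of the knockdowns was also measured. Of the genes called in both, 447 were higher in both, 218 lower in both and 0 opposite, where independent lists would share 21.4 and 14.0. Both tests used the same estimate of each gene's spread, so the calls are tied by the test itself. The counts for independent lists here and below are therefore not a chance level. Among genes without a saturated spot, 26 were higher in both and 211 lower in both, against 1.35 and 13.9 for independent lists. TMEM154, INSIG1, PSAT1, CTH and SCD were among the genes lower in both. Across these unsaturated genes, which are not independent replicates, the fitted ratios correlated at r = 0.689 with a covariance of 0.0236. Unchanged groups simulated against 1 shared mock RNA, assumed to vary like the siRNA RNAs, gave r = 0.667 and a covariance of 0.0225, a difference in covariance of 0.00112. That simulated r is fixed by the assumption of equal variation, and the simulated covariance by the spread between arrays. The comparison therefore cannot tell whether a shared mock RNA underlies the overlap. Over all genes the values were r = 0.774 and 0.0374, against 0.667 and 0.0231, and r was 0.53 without NFYA siRNA array 2. Whether the arrays shared mock RNA is not stated. Single arrays did not group by siRNA target. Over unsaturated genes r was 0.668 between the ELK1 arrays and 0.466 between the NFYA arrays. Between an ELK1 and an NFYA array it ranged from 0.263 to 0.740, highest for ELK1 array 1 with NFYA array 2.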

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

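The tests of saturation, dim spots, dye effect or shared mock RNA, a single array and S phase were chosen after the result was seen, and the correction for probe base composition was added after seeing the data but before its own result was known. Bootstrap intervals below resampled the genes or probes of a list. They treat related genes as independent and hold no variation between arrays or cultures. The medians of 9 gene lists differed between the knockdowns by the set test, each higher under ELK1 siRNA: antigen presentation by 0.32, histones by 0.26, hypoxia and glycolysis by 0.12, NF-kB inflammatory genes by 0.10, fatty acid synthesis by 0.081, the proteasome by 0.066, mitotic genes by 0.057, ribosomal proteins by 0.050 and oxidative phosphorylation by 0.036. With an estimated correlation 0 of these 9 lists passed (smallest adjusted p = 0.527).

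Some named genes lay on one side of 0 on both ELK1 arrays and on the other on both NFYA arrays, a pattern that 6.06% of all genes showed; for these the limma difference did not pass. Above 0 under ELK1 siRNA were RPL35 (fitted difference 1.45, saturated in mock), H3C15 (0.996), CXCL2 (0.80), PSMC3IP (0.77), PQBP1 (0.74), H2BC14 (0.69), H2BC8 (0.68), H2AC20 (0.58), ATP5F1B (0.58), HLA-DRB1 (0.53), CCNA2 (0.44), CDC25C (0.41), NUSAP1 (0.37), HLA-DPA1 (0.37) and HLA-DMB (0.36). Below 0 under ELK1 siRNA were GSG1 (-0.81), SYBU (-0.74), MPP4 (-0.74) and the ELK1 gene itself (fitted difference -0.30), whose siRNA channel was not well above background on both ELK1 arrays, so that its size and sign are not measured.

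Ribosomal protein genes lay above mock in both knockdowns. The test fits saturation of the mock channel as a source: 37 ribosomal protein probes with no saturated spot had a median of -0.069 on the ELK1 arrays (95% bootstrap interval -0.19 to -0.011) and -0.086 on the NFYA arrays, while 170 saturated probes had medians of 0.86 and 0.86. A true change of the saturated transcripts stays open, because their mock level is not measured.

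The medians of the cholesterol, fatty acid and amino acid lists lay below mock in both knockdowns. Their camera calls ended with an estimated correlation (adjusted p = 0.213 to 0.421), a version that rests on 2 residual degrees of freedom. With fry these lists passed under ELK1 siRNA (adjusted p = 0.0118, 0.0405 and 0.0118 in turn) and under NFYA siRNA (0.00662, 0.0288 and 0.0102). No other list passed fry in either comparison with mock. Dye bias that follows probe base composition is argued against: after its correction, which removed -0.13% to 8.51% of an array's variance, the 77 genes had medians of -0.30 and -0.32, with upper interval ends of -0.21 and -0.22. Saturated or dim spots are argued against too, since 68 members free of both had medians of -0.28 and -0.29. A gene-specific dye effect, a mock RNA shared by the arrays and a response to siRNA delivery or to both knockdowns cannot be told apart, because every siRNA sample carried Cy3 and every mock sample Cy5; the median ELK1 minus NFYA difference of 0.046 (interval -0.013 to 0.063) is what each of them predicts. A lower need for sterol and amino acid synthesis after either siRNA may also be involved and was not tested.

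Histone genes were higher under ELK1 siRNA than under NFYA siRNA. The rise rests mainly on the ELK1 siRNA 2 array: array 1 minus the NFYA mean gave 0.096 (interval 0.069 to 0.13), against 0.42 for array 2. Base composition is argued against, as the median on that array was 0.35 after the correction (interval 0.20 to 0.47). More cells in S phase in that sample stays open, since the replication list had a median of -0.060 there with an interval of -0.11 to 0.16. An effect of ELK1 siRNA stays open: without array 2 the median difference was 0.096 rather than 0.26, from 1 ELK1 array. With all arrays 0 of 66 members passed singly, and camera with an estimated correlation gave an adjusted p of 0.527.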

How the results depend on the processing

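Each result was recomputed under every alternative that could be run; saturated spots left out and probe base composition were added after seeing the data. In all, 126 of 167 summary values, 417 of 477 list results and 2444 of 2659 named-gene results kept their direction and side of the threshold, or their count within 1.5 times. These totals include Aquantile scaling and fits that repeat each other, such as those of one siRNA without an array of the other.

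The count for ELK1 siRNA, 1957, became 595 with a 1.5-fold minimum, 4541 at an adjusted p below 0.10, 538 with the deposited scanner ratios, 540 with the value table, 12649 with median centring, 447 without saturated spots and 1216 with the ELK1 arrays fitted alone. Leaving out single arrays gave 671 to 4712. The count for NFYA siRNA, 833, became 406, 1314, 363, 366, 5693, 118 and 1765 under these settings in turn. Leaving out single arrays gave 76 to 1765. With an array left out its group has 1 array, which is assumed to vary like the other group. The count for the difference, 0, became 2 with median centring and 0 to 311 without single arrays (311 without ELK1 siRNA array 1). Aquantile scaling changes no log ratio and so tested nothing.

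The replicate number was run as a block for its effect on counts: the counts became 7080, 3141 and 35. The deviations of same-numbered arrays correlated at 0.38 across genes. There were only 2 pairs, with different siRNA targets, and the labels do not say what a shared number stands for. A component shared by same-numbered arrays stays open, and the main model does not include one.

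With an estimated correlation the numbers of lists passing became 0, 0 and 0, and with fry they were 3, 3 and 1. Lists under NFYA siRNA numbered 13 with median centring. Lists in the difference numbered 3 with the scanner ratios, 3 with the value table, and 5 to 8 without single arrays. The ELK1 gene moved to 0.35 with median centring, -1.46 with the scanner ratios and -1.46 with the value table, and had no value under the stricter filter. The NFYA gene ranged from -0.77 to -0.65 without single arrays. The correlation of the knockdowns, 0.774, ranged from 0.53 to 0.83 without single arrays.

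Median centring, which shifts the median of all genes to -0.19 and -0.13 and leaves intensity-dependent dye effects in place, turned the following below 0. Under ELK1 siRNA: antigen presentation -0.12, oxidative phosphorylation -0.47, proteasome -0.39, mitotic genes -0.39, histones -0.25, heat shock -0.27, PSMB7 -0.026, AURKA -0.025, CKS1B -0.13, CDC25C -0.14, H3-3A -0.024, H2AX -0.18 and HSPD1 -0.056. Under NFYA siRNA: oxidative phosphorylation -0.37, proteasome -0.26 and replication -0.22. In the difference: ribosomal proteins -0.17, oxidative phosphorylation -0.19, proteasome -0.16, mitotic genes -0.15, hypoxia and glycolysis -0.040, fatty acid synthesis -0.084, NF-kB genes -0.0049 and ACSL3 -0.015. Leaving out saturated spots reversed ribosomal proteins under both siRNAs (-0.014 and -0.060) and oxidative phosphorylation under both (-0.032 and -0.076). NDUFA2 in the difference became -0.023 with the scanner ratios and -0.023 with the value table. The ribosomal difference ranged from -0.087 (without ELK1 siRNA array 1) to 0.19 without single arrays. Apart from the construction of these settings, the cause was not tested. The estimated correlation, on 2 residual degrees of freedom, ended every list's call. In the other alternatives that changed the values, the cholesterol and amino acid lists kept their direction and call under both siRNAs, with medians from -0.87 to -0.25. The fatty acid list missed the threshold under ELK1 siRNA without ELK1 siRNA array 1 (adjusted p = 0.0780; 5.32e-05 to 0.0780 over the alternatives). A slide or scan block was not run, because there was 1 slide. Signal over background limits the ELK1 gene, whose siRNA channel was not well above background on both ELK1 arrays.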

Other observations

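The test of MHC class II genes was chosen after the result was seen, as were all genes named here except EGR1, FOS, ATF3 and the antigen presentation genes that the rule for named genes gave. MHC class II genes, here HLA-DRA, HLA-DRB1, HLA-DPA1, HLA-DPB1, HLA-DMA, HLA-DMB, HLA-DOA and the invariant chain CD74, belong to the pathway that presents exogenous peptides. After NFYA siRNA all 8 lay below 0 on both arrays, with medians of -0.22 and -0.21 and no saturated spot, and under ELK1 siRNA 3 of 8 and 0 of 8 lay below 0, with medians of 0.039 and 0.20. In limma 0 of the 8 passed against mock after NFYA siRNA (smallest adjusted p = 0.0545; 5 at an unadjusted p below 0.05). Class I pathway genes (10, among them HLA-B, TAP1 and PSMB9) were higher on the arrays numbered 2: their medians were 0.31 and 1.03 on ELK1 arrays 1 and 2, and -0.12 and 0.49 on NFYA arrays 1 and 2. Median centring turned the class II median under ELK1 siRNA to -0.30 and the class I median under NFYA siRNA to -0.18.

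Class II promoters carry a CCAAT element bound by NF-Y, so a candidate explanation is fewer class II transcripts with less NF-Y. The class II median difference, ELK1 minus NFYA, was 0.36, above all 10000 random lists matched on intensity, of which the highest gave 0.26. Class I pathway genes differed the same way, by a median of 0.44, so the difference is not particular to class II. The group was chosen from the same arrays, so this test cannot decide, and the difference was 0.18 with median centring and 0.40 with the deposited ratios. With an estimated correlation the wider antigen presentation list had an adjusted p of 0.527.

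In limma 0 immediate-early genes passed for the difference between the knockdowns (adjusted p = 0.924 for EGR1, DUSP1, FOS, ATF3 and DUSP6). EGR1 and DUSP1 were at -1.56 and -0.71 under ELK1 siRNA (adjusted p = 0.00120 and 0.0133), while FOS was at 0.81 under NFYA siRNA (adjusted p = 0.00865) and 0.17 and 0.21 on the ELK1 arrays. ATF3 fell in both, by 0.59 and 0.96, and DUSP6 was at -0.44 under NFYA siRNA (adjusted p = 0.0382) and -0.15 under ELK1 siRNA (adjusted p = 0.281). Of the 35 interferon-response genes, 2 rose and 2 fell under ELK1 siRNA, with IFITM1 at -0.58, TRIM22 at -0.62, BST2 at 0.64 and EIF2AK2 at 0.46, and 1 fell under NFYA siRNA (IFITM1, -0.60).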
